A study of Mus musculus with 4 samples.

How the data were processed

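Total RNA from mouse back skin and tail, named as skin in the sample labels and as epidermis in the extraction protocol, was labelled with Cy3 from 200 ng, per the labels' protocols, and hybridised to 4 one-colour Agilent arrays of 1 slide, 1 per group. Array position and group cannot be told apart. Groups were taken from the sample titles. Per the file headers, the deposited processed signal is a spot intensity that Feature Extraction 10.5.1.1 corrected for background without normalization between arrays, while the submitters' processing notes name version 10.7. The raw median pixel intensity of each spot and its local background are deposited beside it, per the file headers. The deposited table of the authors' processed values is on a log2 scale whose making is not stated. Its differences between arrays matched log2 differences of the processed signal plus a constant within 0.001 for 99.4% of probes, so scale and direction were known. Each probe was centred on its median over the 4 arrays, and the medians of the columns were -0.28, 0.10, -0.03 and 0.08 in the order tail control, tail treated, back control and back treated.

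Values were log2 of the processed signal minus each array's 75th percentile over non-control probes. Spots marked as outliers were left out, and repeated spots of a probe were averaged. Saturated spots were kept. Of 41174 probes, 24375 (59.2%) matched 1 gene symbol through their accession in a RefSeq table of assembly GRCm38.p6. The file headers name the older build mm8, so no coordinates are given. The brightest probe represented each gene, which gave 16862 genes usable on all 4 arrays out of 17016 matched symbols. Of the matched symbols, 5779 had 2 or more probes. Between probes of a gene the median SD of the difference was 0.40 in the tail, 0.22 in the back and 0.34 between the untreated skins. Called genes had probes of the same sign in 80.8%, 90.7% and 88.8% of cases.

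A gene was measured when it was well above background and unsaturated on both arrays compared. With 1 array dim, its level was set to the higher of its own signal and the lowest signal well above background on that array, and with 1 array saturated the saturated value stood, which gave a bound in the stated direction. Genes dim or saturated on both had no value. Genes dim or saturated on 1 array also had none where the scaled difference pointed against the direction of the bound. In the tail 4004 genes had no value, of which 1778 were dim on both arrays and 327 saturated on both. Bounds entered list medians at their bound. The numbers of genes measured on both arrays were 12485 in the tail, 12480 in the back and 12092 between untreated skins. Spot error came from the scanner's error per spot. No p-value is given, because 1 array per group leaves no replicate error and genes are not replicates. The number of arrays limits the precision.

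Of 945 entries in 42 gene lists fixed beforehand, 869 were on the array, from 841 different genes. Some lists share members, so they are not independent. The neutrophil list shares Mmp8 and Mmp9 with the metalloproteinases, S100a8 and S100a9 with the wound keratinocyte list, and Il1b with the cytokines. Random lists of the same size were matched in 20 bins of mean level. Lists with fewer than 5 members with a value were not placed. Chance alone would set about 0.4 of 40 lists apart if members varied independently. Members of a list can vary together between animals or samples, so more lists can stand apart without any effect of treatment. Named genes were, per comparison, the 12 with the largest measured difference each way whose other measured probes had the same sign, the 6 each way for the difference of responses, and up to 4 members of each list by size plus members called only as a bound. Clone and predicted-gene names were skipped. Names outside these rules are stated as such. Some genes within these rules are not reported here. The number of genes expected in common is the product of both lists' sizes over the genes compared.

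The calls were tested on simulated arrays made from the real levels, with 50 genes set at each of 4 differences among 16862 genes. The changed genes lay at middle levels. The noise was that of spots only, without variation between animals, differences between probes of a gene or a trend with level. In each of the 3 comparisons simulated, 100% of genes set at log2 differences of 1.5, -1.5, 2.5 and -2.5 were recovered. Of unchanged genes, 7 were called in the simulated tail comparison, 6 in the back and 3 between the skins. With these settings high recovery and few false calls were nearly fixed in advance. A simulated list with raised genes reached the 100th percentile, and 2, 1 and 1 of 100 unchanged lists stood apart.

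Alternatives chosen in advance were normexp background correction with an offset of 50, quantile normalization, centring on the median of detected probes, cyclic loess, measured genes only, no filter, the mean of a gene's probes, outlier spots kept, a difference above 3 spot errors, and the authors' deposited values. Normexp was planned on mean signals, which the files used here do not list, and was run on median signals. Added after the data were seen were the brightest unsaturated probe, a signal of at least 200 on both arrays without saturation, and scaling to 4 unsaturated spike-in probes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1, and plots used matplotlib 3.10.9.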

Results

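Gene expression was measured in mouse skin 48 h after a photodynamic treatment, which makes a burst of reactive oxygen species in the tissue. Methyl aminolevulinate, a precursor from which cells make the light-absorbing heme intermediate protoporphyrin IX, was applied as a cream. After 2.5 h in darkness the skin received red light of 636 nm, at 10 J/cm2 on the tail and 2.5 J/cm2 on the back. The 4 groups were tail control, tail treated, back control and back treated, with 3 animals per group by the study design. Each group was represented by 1 one-colour array, and it is not stated whether the RNA of the 3 animals was pooled. There were therefore no replicates, no difference below has a replicate check, and none was tested. All values compare these 4 arrays.

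The sample labels name tail skin and back skin, while the extraction protocol speaks of tail epidermis, so the layer taken from the tail is uncertain. The 75th percentile of the processed signal was 7261 on the tail control array, 909 on the tail treated array, 1860 on the back control array and 1204 on the back treated array. Of 16862 named genes, 14953, 14287, 13938 and 13355 were well above background on these arrays in the same order, and 1668, 330, 666 and 334 were saturated. Repeated spots of a probe within an array had a median SD of 0.068, 0.065, 0.054 and 0.055 on the log2 scale. Differences are given as log2 values after each array was scaled to its 75th percentile, and a gene was called higher or lower from a 2-fold difference. Where a gene was saturated or not well above background on 1 of the 2 arrays, only a bound could be given, written as "at least". The median scanner error of a difference was 0.20, which covers spots and not animals. Gene lists were fixed before the data were examined, and a list stood apart when its median difference lay in the lowest or highest 0.5% of 10000 random lists matched on expression level.

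The first comparison asked how tail skin differed 48 h after treatment. In the treated tail array, 9 of 22 genes that neutralise oxidants, 8 of 14 genes of activated keratinocytes and 9 of 19 lipid genes were higher, although the oxidant and lipid lists no longer stood apart after cyclic loess. The activated keratinocyte list also stood apart in back control minus tail control, a pair without treatment, with 11 of 13 higher and 2 lower. In the treated tail array, 7 of 13 immediate early genes and 5 of 7 basal epidermis genes were lower. The glutathione transferase Gsta4, which conjugates products of lipid peroxidation, was 4.25 higher, or 19.0-fold. The wound keratin Krt6b was 3.74 higher and the alarmin S100a8 at least 44.9-fold higher, and after cyclic loess they were higher by 2.56 and by at least 4.54 on the log2 scale. The AP-1 subunits Fosl1 and Fosb differed by -4.41 and -3.12, and the cytokine Tnf by -4.77. In all, 3496 genes were higher and 842 lower, so 80.6% of the calls were higher.

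Of the NRF2 and antioxidant list, 9 of 22 members with a value were higher and none lower, with a median of 0.91. Beside Gsta4, the members with the largest differences were the glutathione peroxidases Gpx2 at 2.19 and Gpx3 at 1.79 and the transferase Gsta3 at 1.88. After cyclic loess, which removes differences that depend on brightness, this median was 0.05 and the list no longer stood apart, at the 98.2nd percentile. Among wound and hyperproliferation keratinocyte genes, 8 of 14 were higher and 1 lower (median 1.25, and 0.55 after cyclic loess), including the defensin Defb3 at 2.29 and the stefin Stfa2 at 2.02. In the sebocyte and lipid synthesis list 9 of 19 were higher (median 0.99), led by Cidea at 2.99, the fatty acid elongase Elovl3 at 2.66 and the cholesterol-esterifying enzyme Soat1 at 2.48. Adipocyte markers (10 of 14 higher, 1 lower, median 1.80) included the lipid droplet protein Plin4 at 2.54 and Fabp4 at 2.20. Neutrophil markers (10 of 13 higher, median 1.83) included the protease Elane at 3.02. After cyclic loess the sebocyte, adipocyte and neutrophil lists no longer stood apart, with medians of 0.33, 0.79 and 0.76. That correction put Stfa2 at 0.94, under 2-fold, and Cidea at 1.93, Fabp4 at 1.33 and Elane at 1.95. Red blood cell genes were higher in 4 of 5 cases with a median of 2.02, among them the globins Hbb-bt at 4.35 and Hba-a1 at 3.45. In back control minus tail control, a pair without treatment, the wound keratinocyte and neutrophil lists also stood apart as higher, with medians of 1.70 and 2.35. For these lists a property of the tail control array cannot be told apart from treatment. The NRF2, sebocyte, adipocyte and red blood cell lists did not stand apart in that pair.

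Immediate early genes, which are switched on within minutes of a stimulus, were lower in 7 of 13 cases and higher in none, with a median of -1.04. Of the 13 values 6 were bounds, and members measured on both arrays had a median of -0.90. Atf3 was at least 52.5-fold lower, while Egr3 differed by 0.93. The other 10 members on the array had no value. Basal epidermis genes were lower in 5 of 7 cases and higher in none, with a median of -1.34. Among them were the integrins Itgb1 at -2.32, Itga6 at -2.05 and Itga3 at -1.08, which anchor keratinocytes to the basement membrane, and the laminin chain Lamb3 at -1.34. The remaining 6 members had no value. On the same pair of arrays, pooled markers of fibroblasts, endothelium, fat, muscle and red blood cells were higher in 52 of 78 cases and lower in 6, with a median of 1.38, or 0.91 after cyclic loess. Where the bright tail control array was saturated, a gene could only be called lower. Cytokines and chemokines stood apart on the lower side, with 10 higher, 8 lower and a median of -0.25, yet members measured on both arrays had a median of 0.72. Cxcl10 was at least 117-fold lower, Ccl20 at least 44.3-fold lower and Il1a differed by -2.45, whereas Osm was 3.36 and Il17f 2.63 higher.

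Several lists of interest for this treatment did not stand apart in the tail. Of the mitosis genes 24 of 28 differed by less than 2-fold (median 0.05), as did 25 of 29 DNA replication genes (median -0.11). Heme synthesis and iron genes had a median of 0.39 with 15 of 17 within 2-fold. The exceptions were the iron exporter Slc40a1 at 2.02, or 1.06 after cyclic loess, and the porphyrin exporter Abcg2 at -1.94. The p53 and apoptosis list had a median of -0.27, at the 0.93rd percentile. Markers of fibroblasts (13 of 21 higher, 4 lower, median 1.30), endothelium (9 of 15 higher, median 1.54) and skeletal muscle (16 of 23 higher, 1 lower, median 1.17) were mostly higher without standing apart from genes of like level. After cyclic loess the fibroblast and endothelial lists stood apart, with medians of 0.91 and 1.08. Reference genes had a median of 0.18, with 7 of 8 within 2-fold and Actb at 2.53.

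The genes with the largest measured differences in the tail were mostly read by a single probe, 11 of the 12 higher and 10 of the 12 lower ones. Higher were the G protein subunit Gng8 at 8.51, Pramel39 at 6.66, the sarcomere-associated ligase Trim55 at 5.78, the helicase Ddx25 at 5.73, the transcription factors Pou4f3 at 5.48, Pax4 at 5.12 and Tcf23 at 4.88, the myosin light chain Myl1 at 5.44, Pp2d1 at 5.35, the nuclear receptor Nr1i3 at 4.87, Lyg1 at 4.86 and Olfr822 at 4.65. Lower, beside Tnf and Fosl1, were the small leucine-rich proteoglycan Ogn at -4.68, the natriuretic peptide Nppb at -4.64, the stromelysin Mmp3 at -4.34, the endothelin Edn2 at -3.93, Lect2 at -3.89, the transcription factors Ets1 at -3.78 and Rel at -3.75, Matn4 at -3.72, the adhesion molecule Icam1 at -3.67 and the EGF receptor ligand Ereg at -3.64. With normexp background correction Matn4 and Icam1 were at 1.03 and 0.032 instead. Gng8 and Tcf23 were also 9.35 and 6.85 higher on the back control than on the tail control array, a pair without treatment. Several of the higher genes were dim on the tail control array, where the lowest signal well above background was 21.2. Pax4, Myl1, Pramel39, Nr1i3 and Olfr822 had signals of 26.0, 31.1, 33.8, 52.9 and 58.0 there, and the others ran from 54.5 for Gng8 to 778 for Ddx25. The large values of the dim ones thus rest on low signals of the tail control array.

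Among genes measured on both tail arrays only, the neutrophil, adipocyte and cytokine lists no longer stood apart, and without a filter the wound keratinocyte and red blood cell lists did not. The split of tail calls depended on the scaling. The share of higher calls was 80.6% with the 75th percentile, 54.6% after cyclic loess (1952 higher, 1624 lower), 57.8% after quantile normalization, 91.5% after normexp background correction and 1.37% with spike-in scaling.

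**Figure D1:**
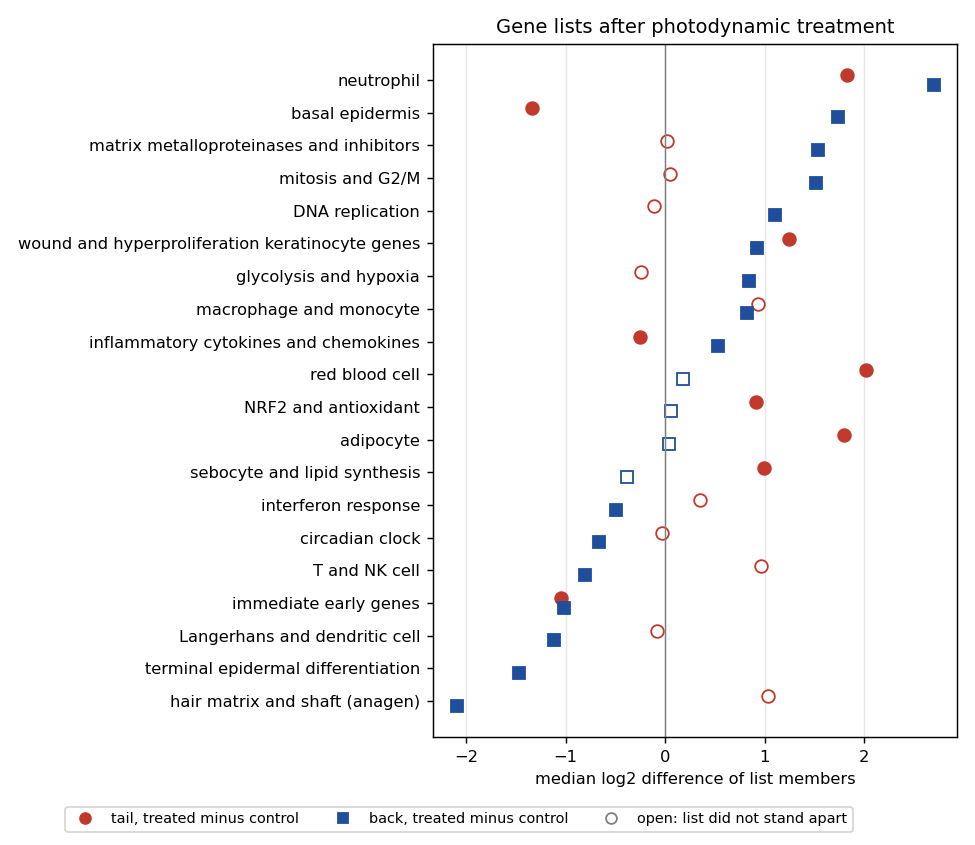
Median log2 difference (horizontal axis, treated minus control) of each gene list that stood apart in the tail or the back. Circles are the tail and squares the back, with open symbols for lists that did not stand apart and no circle where too few members had a value. Basal epidermis genes had a median of -1.34 in the tail and 1.73 in the back, and immediate early genes of -1.04 and -1.02.

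The second comparison asked the same of back skin. In the treated back array, most genes of mitosis, basal epidermis, metalloproteinases and their inhibitors, and neutrophils were higher. So were 15 of 29 DNA replication genes and 12 of 34 cytokine and chemokine genes. Most genes of terminal epidermal differentiation, the hair shaft and Langerhans cells were lower, as were 7 of 18 T and NK cell markers. The neutrophil chemoattractant Cxcl3 was 9.05 higher, a 529-fold difference, and the keratinocyte cytokine Il24 was 5.83 higher. The suprabasal keratin Krt2 differed by -6.54 and the neuropeptide gene Nmu by -6.91. In all, 1826 genes were higher and 1698 lower.

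Mitosis genes were higher in 23 of 29 cases and lower in none, with a median of 1.52. They included the spindle checkpoint kinase Bub1 at 2.13, the mitotic kinases Plk1 at 1.99 and Aurka at 1.91, and Hmmr at 1.92. DNA replication genes were higher in 15 of 29 cases and lower in 1 (median 1.1004), led by the transcription factor E2f1 at 2.69, thymidine kinase Tk1 at 2.25 and the polymerase subunit Pole at 1.93. Basal epidermis genes were higher in 7 of 10 cases (median 1.73), with Itga3 at 2.69, Itgb1 at 1.87 and Lamb3 at 1.78. Wound keratinocyte genes had a median of 0.92, with 6 of 15 higher and 3 lower. The receptor Plaur was 2.02 higher, while the interleukin genes Il1f6 and Il1f8 differed by -3.85 and -2.30. Glycolysis and hypoxia genes had a median of 0.85, with 4 of 15 higher and none lower. The lactate transporter Slc16a3 was the highest at 4.06.

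Of matrix metalloproteinases and their inhibitors, 11 of 18 were higher and 1 lower, with a median of 1.54. The collagenases Mmp1a and Mmp13 were 4.51 and 3.81 higher, and the matrix glycoprotein Tnc 3.92. Cytokines and chemokines were higher in 12 of 34 cases and lower in 5 (median 0.53). Ccl3, Cxcl1 and Ccl4 were 5.26, 4.34 and 3.91 higher, and Cxcl5 at least 73.3-fold higher. Neutrophil markers were higher in 11 of 15 cases and lower in 1 (median 2.70). Of the 15 values 5 were bounds, and members measured on both arrays had a median of 1.61. Among the higher ones were Retnlg at 5.47, the lectins Clec4e at 4.25 and Clec4d at 3.56, and the formyl peptide receptor Fpr2 at 4.15. Macrophage markers were higher in 9 of 20 cases and lower in 1 (median 0.83), with the mannose receptor Mrc1 at 3.34 and Cd163 at least 40.0-fold higher.

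Terminal differentiation genes were lower in 9 of 14 cases and higher in none, with a median of -1.46. Beside Krt2 they included the lipoxygenase Alox12b at -2.03 and the cornified envelope protein Ivl at -1.98, and the protease Casp14 was at least 8.05-fold lower. Hair matrix and shaft genes were lower in 17 of 24 cases and higher in 1 (median -2.09), with the keratin-associated proteins Krtap13 at -5.17 and Krtap3-2 at -3.99 and the keratin Krt84 at -4.77. Langerhans and dendritic cell markers were lower in 8 of 14 cases and higher in none (median -1.12). The Langerhans lectin Cd207 differed by -1.67, Epcam by -1.63, the invariant chain Cd74 by -1.55 and the class II gene H2-Aa by -1.25. T and NK cell markers were lower in 7 of 18 cases (median -0.80), with Cd4 at -4.85, Cd8a at -1.52 and Cd3g at -1.41. Interferon response genes were lower in 9 of 26 cases (median -0.50), led by Irf7 at -3.04. Circadian clock genes had a median of -0.66 with 5 of 18 lower, among them Nr1d1 at -2.34 and Tef at -1.78, and Bhlhe40 higher at 1.34. Immediate early genes were lower in 9 of 18 cases (median -1.02), with Fosb at -2.55, Nr4a2 at -1.95 and Jun at -1.52.

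In the back, the NRF2 and antioxidant list did not stand apart, with 10 of 31 higher, 5 lower and a median of 0.06. Gsta4 was nevertheless 4.56 higher, Gsr 2.12 and the cystine transporter Slc7a11 2.04, while Srxn1 differed by -2.30. Heme synthesis and iron genes had a median of 0.28, with Slc40a1 at -2.66 and Abcg2 at 2.25. The p53 and apoptosis list had a median of -0.13. With a signal of at least 200 required on both arrays, the wound keratinocyte, cytokine and interferon lists no longer stood apart, the first 2 with medians of 0.061 and 0.085. Nor did wound keratinocyte genes among measured genes only (median 0.49), interferon genes with a requirement of 3 spot errors, Langerhans markers with normexp, or terminal differentiation without a filter.

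Of the genes with the largest measured differences in the back, 10 of the 12 higher and 11 of the 12 lower ones had a single probe. The higher ones included the myeloid receptor Cd300lf at 6.77, the secreted hormone Stc2 at 6.46, the prolactin family member Prl2c3 at 6.42, Cyp2a5 at 5.82, the simple-epithelial keratin Krt18 at 5.78, osteopontin Spp1 at 4.87 and Rapgef3 at 4.77. The lower ones included the protease inhibitor Wfdc12 at -5.65, Krtap6-5 at -5.20, Olfr424 at -5.20, Plaat1 at -4.99, the transcription factor Lhx6 at -4.95, Scgb1b27 at -4.80 and the water channel Aqp5 at -4.69. The share of higher calls was 51.8%, and 20.04% with spike-in scaling.

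The responses of the skins were then set side by side over the 11281 genes measured on all 4 arrays. Across genes, which are not independent replicates, the differences in tail and back had a Pearson r of 0.0427 and a Spearman rho of 0.0148. The r was 0.0698 after cyclic loess, 0.0645 with outlier spots kept, 0.110 with a signal of at least 200 and 0.158 with normexp. There were 406 genes higher in both, against 373 for independent lists of those sizes, and 124 lower in both, against 84.1. Gsta4 was higher in both, and the EGF receptor ligand Ereg was lower in both, at -3.64 and -3.53. Myl1 was 5.44 and 3.15 higher, and Fosb and the growth factor binding protein Igfbp3 were lower in both, the last at -3.29 and -2.48. The retinoic acid synthesis enzyme Aldh1a3, at 4.29 and 3.98, and the platelet chemokine Pf4, at 3.44 and 4.66, were chosen after their values were seen. Gsta4 and Aldh1a3 were also 1.76 and 2.83 higher on the back control than on the tail control array. The share in common was 270 genes higher in both (225 for independent lists) and 213 lower in both (139) after cyclic loess.

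The back response exceeded the tail response by 4-fold or more for 472 genes, and the reverse held for 1183. These counts were 646 and 713 after cyclic loess, 636 and 724 after quantile normalization, 193 and 3141 with normexp, and 3301 and 181 with spike-in scaling, with the larger count on the other side only for the last of these. Mmp3 differed by -4.34 in the tail and 3.34 in the back, Cxcl1 by -2.06 and 4.34, and Tnc by -2.22 and 3.92. With normexp background correction the tail values of Cxcl1 and Tnc were 2.51 and 0.055, so that only Mmp3 of these 3 kept opposite directions. Nppb, Tnf and Spp1 also lay higher in the back response, by 5.26, 5.58 and 5.49. On the other side, Gng8 differed by 8.51 in the tail and -1.31 in the back, Nmu by 0.70 and -6.91, Ugt3a1 by 2.62 and -3.81, and Aqp5 by 1.65 and -4.69. With spike-in scaling, which moved all tail differences by -2.03, Nmu and Aqp5 were lower in the tail too. Gng8, read by 1 probe, had a signal of 54.5 on the tail control array. On the tail treated, back control and back treated arrays it was 2488, 9126 and 2379. Its tail value thus rests on a low signal of the tail control array. With 1 array per group these differences of responses were not tested. Site and light dose, 10 J/cm2 on the tail and 2.5 J/cm2 on the back, cannot be told apart in them.

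**Figure D2:**
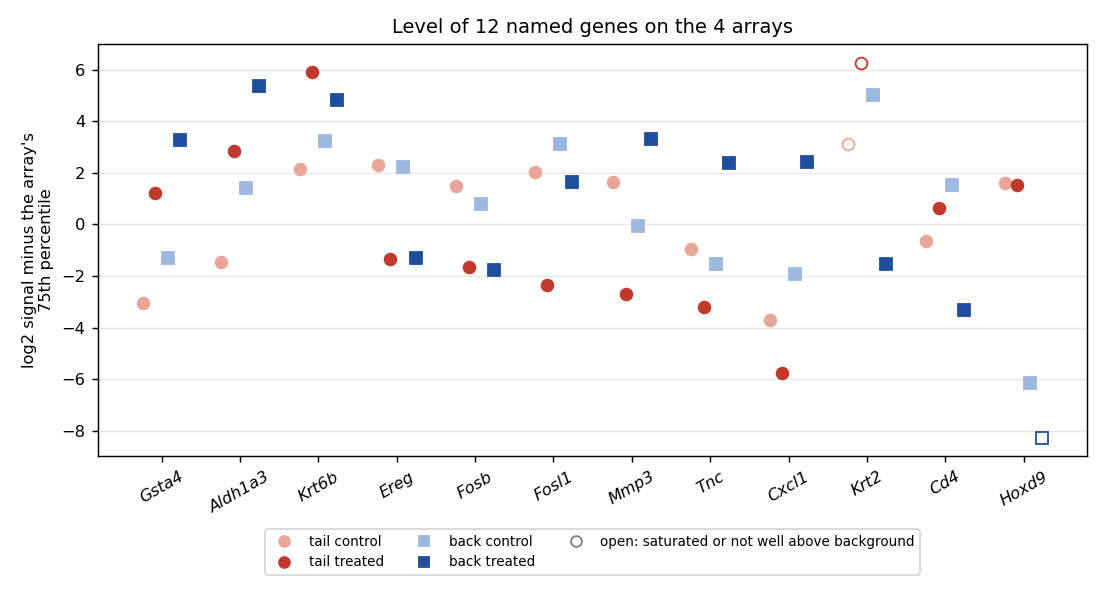
Level of 12 genes on each array, as log2 signal minus the array's 75th percentile (vertical axis). Circles are tail and squares back arrays, dark symbols treated and pale ones control, and open symbols mark saturated or dim spots. Gsta4 was higher in both treated arrays (4.25 and 4.56), while Mmp3 differed by -4.34 in the tail and 3.34 in the back.

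The third comparison set the untreated skins against each other, back control minus tail control, as the background of the treatment comparisons. The untreated back array had higher interferon and chemokine genes and higher markers of Langerhans cells, T cells, neutrophils and macrophages, while the B and plasma cell list (3 of 7 higher) and the mast cell list (4 of 8 higher, 2 lower) did not stand apart. In the untreated tail array 18 of 24 hair shaft, 7 of 11 pigment cell and 9 of 16 posterior Hox genes were higher, some only as bounds. The cytokine Tslp was 6.48 higher in the back and the cyclooxygenase Ptgs2 6.23. The keratin-associated protein Krtap5-2 differed by -9.22 and Hoxd9 by -7.75. In all, 3507 genes were higher in the back and 2206 lower.

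Interferon response genes were higher in 21 of 25 cases and lower in none, with a median of 2.70, including Oasl2 at 5.03, Ifit1 at 4.55 and Rtp4 at 4.35. T and NK cell markers were higher in 14 of 18 cases (median 2.33), including the interleukin receptor chain Il2rb at 3.82 and Cd3d at 3.60. Langerhans and dendritic cell markers were higher in 13 of 14 cases (median 2.26), among them Ly75 at 3.84 and Cd207 at 3.36. Cytokines and chemokines were higher in 25 of 31 cases and lower in 1 (median 2.16), with Ccl4 at 5.03 and Il1b at 4.37. Neutrophil markers had a median of 2.35 (10 of 12 higher), macrophage markers of 2.02 (13 of 19 higher, 2 lower), metalloproteinases of 1.61 (9 of 16 higher, 2 lower) and wound keratinocyte genes of 1.70 (11 of 13 higher, 2 lower). Fibroblast and dermal matrix genes were higher in 12 of 19 cases and lower in 4 (median 1.36), with the collagen Col3a1 at 2.59 and Pdgfrb at 2.93 but decorin, Dcn, at -3.41.

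Hair matrix and shaft genes were lower in the back array in 18 of 24 cases and higher in 2 (median -3.76). Of these values 15 were bounds, and members measured on both arrays had a median of -1.41. The peptidylarginine deiminase Padi3 differed by -6.43, Hoxc13, a regulator of hair keratins, by -4.25, and the hair keratin Krt86 was at least 192-fold lower. With a signal of at least 200 required on both arrays, 2 members were higher and 2 lower, and the median was 0.57. Inner root sheath genes had a median of -4.22 with 6 of 9 lower and 2 higher, mostly as bounds, such as Krt26 at least 235-fold lower. The 3 members measured on both arrays had a median of 1.43 and included Tgm6 at -5.43. Melanocyte genes were lower in 7 of 11 cases and higher in none (median -2.35), with the pigment enzymes Tyrp1 at -4.54 and Dct at -3.54 and the melanosome protein Pmel at -4.46. Posterior Hox genes were lower in 9 of 16 cases and higher in 2 (median -2.31). Hoxd10 was at least 182-fold and Hoxa10 at least 57.3-fold lower, whereas Hoxa13 was 3.89 higher in the back. Members measured on both arrays had a median of 0.07.

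Other genes with large measured differences were Gng8 at 9.35, the sphingolipid desaturase Degs2 at 8.52, Pkib at 8.37, Mrgprb3 at 8.03 and the mast cell receptor Mrgprb2 at 6.94, Tspan8 at 7.87, the cholesterol hydroxylase Ch25h at 6.96 and H2-Q8 at 6.91. On the lower side were Krtap19-5 at -8.39, Vsig8 at -7.46, the gluconeogenic enzyme Fbp1 at -7.08, Tmem45a2 at -6.74, Krtap4-13 at -6.38, Diras1 at -6.19 and the nucleotide receptor P2ry2 at -5.76. The share of higher calls was 61.4%, and 48.9% after cyclic loess, 47.3% after quantile normalization and 16.7% with spike-in scaling. With a signal of at least 200 required, the fibroblast, metalloproteinase, macrophage and T and NK cell lists no longer stood apart, nor did posterior Hox genes measured on both arrays or fibroblast genes with normexp or without a filter. As the protocol names tail epidermis and the labels tail skin, a difference in the sampled layer is not excluded.

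**Figure D3:**
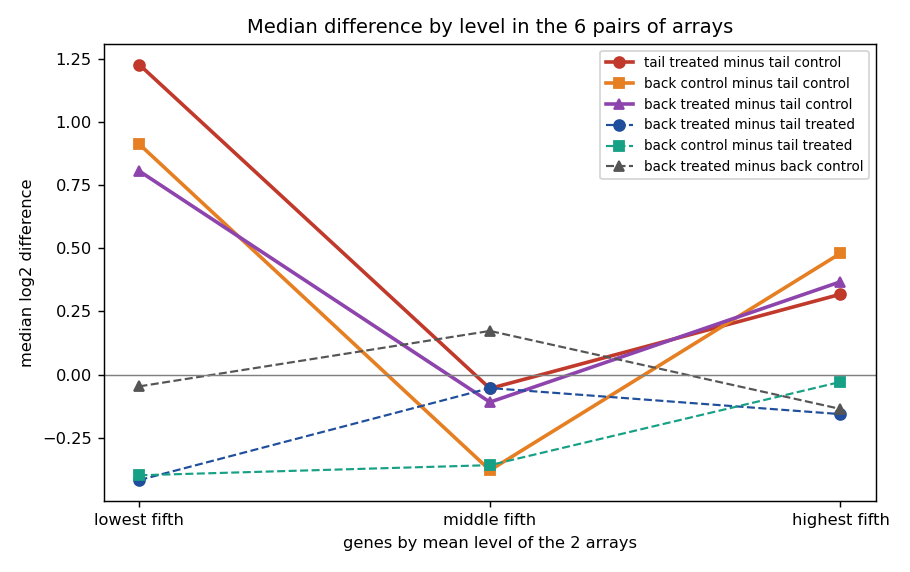
Median log2 difference (vertical axis) of genes in the dimmest, middle and brightest quintile by mean level (horizontal axis) for the 6 pairs of arrays. Solid lines are pairs with the tail control array. Its pairs lay at 1.23, 0.91 and 0.80 for the dimmest genes, and the other pairs at -0.42, -0.40 and -0.05.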

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

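The tests of level trends and of a lower keratinocyte share were chosen after the values they use had been seen, and the others before. Differences between tail and back below were picked out because the arrays moved in opposite directions, and none was tested. Site and light dose cannot be told apart in them.

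Basal epidermis genes had medians of -1.34 in the tail and 1.73 in the back, a difference of 3.08. Cytokines and chemokines differed by 0.787, from -0.25 to 0.53, but the tail median was 0.72 among measured members only and 2.06 with normexp, so the opposite direction does not hold in either case. There were 290 genes higher in the tail and lower in the back, and 111 the other way, against 301 and 104 for independent lists. Among single genes, Mmp3 differed between the responses by 7.68, Cxcl1 by 6.39 and Tnc by 6.14, but with normexp the tail values of Cxcl1 and Tnc were 2.51 and 0.055, no longer opposite to the back. Gng8 differed by -9.82, Ugt3a1 by -6.43, Aqp5 by -6.34, Idi2 by -6.14 and Cd4 by -6.13. Spike-in scaling moved all tail differences by -2.03. The tail values of Aqp5 and Cd4, at 1.65 and 1.29 before, then became negative as in the back, while Gng8, Ugt3a1 and Idi2 kept opposite directions. The signal of spike-in probes, which the comparisons do not use, was 1.96 times higher on the tail control array than on the tail treated array, while the 75th percentile of the mouse probes was 7.99 times higher.

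The first pattern is that 80.6% of calls in the tail were higher. If brightness caused this, dim genes should lie above mid-level genes in each pair with the tail control array and not in other pairs. The excess was 1.28, 1.29 and 0.91 in the pairs with it and at most 0.36 in size in the others, but it did not follow the brightness ratios of 7.99, 3.90 and 6.03. Brightness cannot be told apart from any other property of the tail control array, since the pairs share arrays and are not independent. Treatment of the tail stays open too, though the back control minus tail control pair, at 1.29, holds no treated array.

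The next pattern is that markers of dermis, vessels, fat, muscle and blood were higher in the treated tail array, where basal epidermis genes were lower (median -1.34). Pooled, 52 of 78 were higher and 6 lower, with a median of 1.38. Brightness as the whole cause would bring the median near 0 after cyclic loess, and it was 0.91, above all matched random lists. More dermis in the treated preparation than in the tail control one may contribute. After cyclic loess the fibroblast median was also 0.91, set by the same gene, and the endothelial one 1.08. Col1a1, Col1a2 and Col3a1 were 1.09, 1.36 and 1.78 higher before that correction, but 4 of 21 fibroblast members were lower. A difference in dermis thus stays open, as does treatment, untested. In back control minus tail control, a pair without treatment, the fibroblast list stood apart too, with 12 of 19 higher and 4 lower. Endothelial, adipocyte, muscle and red blood cell lists there had more members higher than lower but did not stand apart. That pair also differs in site, so a property of the tail control array stays open as well.

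The last pattern is that neutrophil markers were higher and Langerhans and T cell markers lower in the treated back array. A lower share of keratinocytes alone would raise all of them, but the Langerhans median was -1.12 and the T cell median -0.80. These values do not test a smaller share of the whole epidermis, with the Langerhans and T cells in it. Cyclic loess left the neutrophil and Langerhans medians 3.56 apart, but it moved the median of all genes by only 0.032 in the back and so was no test of brightness. A trend with expression level as the cause is argued against by the medians of dim, mid-level and bright genes. They differed by at most 0.31, against a gap of 3.82. The neutrophil median in that gap, 2.70, included bounds and was 1.61 among members measured on both arrays. A hypothesis left open is a change in the immune cells of the treated back, which may differ between animals, and 1 array cannot test it.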

How the results depend on the processing

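No paired analysis was possible because each group had 1 array and its number is only a name. The unsaturated probe, the signal of at least 200 and spike-in scaling were chosen after seeing the data. Centring on detected probes, measured genes only, the mean of probes, outlier spots kept, the requirement of 3 spot errors, the authors' deposited values and the brightest unsaturated probe kept every count within 1.5 times its value. The other settings moved the following counts, and the correlation where given.

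With normexp, the tail had 5739 higher and 534 lower genes, the difference of responses 193 and 3141, and r was 0.158. The added offset of 50, the background model and the use of median signals entered together, so their parts cannot be told apart. With quantile normalization the tail had 2110 and 1542, and 724 genes had the larger tail response. With cyclic loess these were 1952, 1624 and 713, with 270 genes higher and 213 lower in both. Without a filter, 6243 genes were higher in the tail and 5926 in the untreated back, 2787 had the larger tail response and 680 were higher in both, as dim and saturated genes then counted. With a signal of at least 200, fewer genes entered, and the tail had 1232 and 387, the back 1194 and 1011, the untreated skins 2073 and 1349, the difference of responses 208 and 454, both responses 195 and 74 in common, and r was 0.110. With spike-in scaling, a constant per array, the tail had 141 and 10156, the back 879 and 3508, the untreated skins 1179 and 5902, the difference of responses 3301 and 181, and 14 and 2158 in common. It moved all tail differences by -2.03, back by -0.47 and untreated skins by -1.05, so all directions hold relative to the array's other genes. The median of all genes moved by 0.41 (normexp), -0.19 (quantile) and -0.38 (cyclic loess) in the tail, and by -0.18 and -0.19 with the last 2 between untreated skins.

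Gene lists are given below by percentile where a setting changed whether they stood apart, and the cause was not tested. In the tail, the NRF2 list was at 98.97 with normexp, 98.15 with cyclic loess and 99.225 without a filter. The sebocyte list was at 98.98 (quantile), 99.14 (cyclic loess), 99.29 (no filter) and 99.47 (mean of probes). The adipocyte list was at 58.66 (normexp), 99.45 (quantile), 99.29 (cyclic loess), 99.375 (measured only) and 99.47 (unsaturated probe). The neutrophil list was at 97.96 (normexp), 99.415 (detected probes), 99.45 (cyclic loess), 82.96 (measured only), 98.88 (no filter) and 99.45 (unsaturated probe). Cytokines were at 5.96 (normexp), 35.66 (measured only) and 2.155 (signal of 200), and without a filter wound keratinocyte genes were at 99.19 and red blood cell genes at 99.41. Tail lists that came to stand apart were p53 and apoptosis at 0.12 (normexp) and 0.35 (no filter), circadian clock at 0.27 (normexp), hair follicle stem cells at 99.85 (normexp), 99.69 (no filter) and 99.7 (signal of 200), fibroblast at 99.93 (quantile) and 99.91 (cyclic loess), endothelial at 99.72 (cyclic loess), and hair matrix at 99.56 (detected probes), 99.79 (cyclic loess), 99.82 (measured only), 99.66 (no filter), 99.64 (mean of probes), 99.61 (3 spot errors) and 99.95 (signal of 200).

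In the back, wound keratinocyte genes were at 96.13 (measured only) and 57.895 (signal of 200), cytokines at 59.8 and interferon genes at 16.32 with the latter, interferon genes at 0.85 with 3 spot errors, Langerhans markers at 0.87 with normexp and terminal differentiation at 5.8 without a filter. Inner root sheath came to 0.42 with normexp and the NRF2 list to 99.6 with a signal of 200. Between untreated skins, fibroblast genes were at 98.285 (normexp), 99.19 (no filter) and exactly at the upper limit with a signal of 200. That setting also put metalloproteinases at 74.915, macrophages at 97.27, T and NK cells at 94.87 and, reversed, hair matrix at 88.65 with 4 called members left. Posterior Hox genes were at 30.455 (measured only) and 0.505 (3 spot errors). Wnt signalling came to 0.21 (quantile), 0.12 (cyclic loess), 0.355 (no filter), 0.13 (mean of probes) and 0.39 (unsaturated probe), immediate early genes to 99.93 (no filter) and 99.98 (signal of 200), and mitosis to 0.25 (signal of 200).

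Among named genes, 1969 of 2298 alternative values, spike-in scaling aside, moved by less than the spot error and 325 by more without changing sign. Much of this was fixed in advance. Measured genes only, no filter, 3 spot errors and a signal of at least 200 keep or drop a measured gene without changing its value. Centring on detected probes and the authors' values add only a small constant per array. The count is thus no measure of how stable the named genes are. In the tail 4 changed sign with normexp, to 1.03 for Matn4, 0.032 for Icam1, 0.055 for Tnc and 2.51 for Cxcl1, and the cause was not tested.

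Of lists that stood apart, 2 of 9 in the tail, 11 of 16 in the back and 7 of 13 between untreated skins did so in every alternative that gave a value, and 5, 16 and 13 after cyclic loess. Signal over background limits dim genes on the dimmer arrays, and saturation limits bright genes on the tail control array.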

Other observations

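Gene families defined by symbol after the data were seen gave further contrasts. Laminins were higher in 7 of 9 cases in the treated back, with a median of 1.22. In the treated tail the laminin median was -1.16, with 4 of 8 lower, including Lamc1 at -1.73, and 2 higher, Lamc3 at 2.38 and Lama4 at 1.40, or 5 lower and 1 higher after cyclic loess. Genes with symbols like those of integrins had a median of 0.44 in the tail, with 6 of 24 higher and 4 lower. In the back it was 0.45, with 8 of 24 higher and 1 lower, including Itga7 at 3.05 and Itga5 at 2.54. This set also took in like-named genes such as Itgbl1, at 2.41 in the tail, Itgb1bp1 and Itgb1bp2. The tail median was -0.12 after cyclic loess. Genes named as C-type lectins were higher in 11 of 15 cases in the tail, or 6 after cyclic loess, and none was lower. In the back 8 of 16 were higher and 2 lower, Clec16a at -1.75 and Clec2g at -1.70. Between untreated skins 10 of 16 of these lectin genes were higher in the back and 1 lower, with a median of 1.46. Genes with the H2 prefix of MHC genes were lower in 7 of 16 cases and higher in none in the treated back, with a median of -0.85. Between untreated skins they were higher in the back in 13 of 15 cases, with a median of 2.60. The 1 lower was H2-Ke6 at -1.86. Keratin-associated proteins were lower in the untreated back in all 28 cases with a value, with a median of -6.02, and again lower in 17 of 27 cases after treatment.

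Glutathione transferases went both ways in the back, where 3 of 21 were higher, with Gsta4 at 4.56, and 6 were lower, with Gsta2 at -2.33 and Gstm5 at -2.17. In the tail 7 of 18 were higher and none lower, with a median of 0.76, which was 0.05 after cyclic loess.

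Olfactory receptor genes were higher in 330 of 454 cases and lower in 5 in the treated tail, with a median of 1.33. In the untreated back they were higher than in the untreated tail in 189 of 387 cases, and in the treated back 11 of 361 were higher and 56 lower. After cyclic loess 136 were higher and 12 lower in the tail.

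Xist, which is expressed from an inactive X chromosome, was not well above background on any of the 4 arrays, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background on all of them.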
